A study of Mus musculus with 51 samples.

How the data were processed

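RNA from 51 samples was measured on Affymetrix whole-genome mouse arrays, with biotin-labelled cRNA per the labels' protocols. The deposited values are probe set intensities on a linear scale, made with RMA per the submitters' processing notes, which state no version or settings. The 3 cell types have 3 different distributions of the deposited intensities, so each was treated as normalized apart. All 51 value columns were used (0 unused). The intensities were turned into log2 values and not normalized further.

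Samples were grouped by their labels into 17 groups of 3 arrays. SV40 MEFs and MIN6 cells with constructs are pools of cells transduced with retrovirus and selected with puromycin, per the labels' protocols.

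Of 45101 probe sets, 64 were array controls, 34945 carried 1 gene symbol, 932 several and 9160 none. The symbols, 18193 in all, came from the table of RefSeq genes. Probe sets whose highest group mean lay below the 40th percentile of all group means of the cell type were left out. The brightest remaining probe set stood for each gene, which gave 13674 genes in primary MEFs, 13469 in SV40 MEFs, 13179 in MIN6 cells and 16019 for contrasts across both lines. Gene order came from the same table (assembly GRCm38.p6) and was used only to find which genes neighbour each other.

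Each cell type was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3, with the data.table package in version 1.17.8) with a mean per group and no covariate. The 25 comparisons were 12 of a knock out or construct with its control, 5 direct contrasts of constructs, 5 differences between effects and 3 contrasts between WT groups. All p-values are two-sided, adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Where a count at an unadjusted p below 0.05 is given, a share of about 0.05 of the tested genes would pass without any difference. The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule names the Hmgn genes, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap (6 in direct contrasts), and up to 4 members of each list. The sex-linked genes, Actb control probe sets and genes common to several pools were read as checks.

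Of 21 gene lists and 11 lists of cell type markers, those with at least 3 tested genes (31 in MEF comparisons, 29 in MIN6 comparisons) were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Where 2 values follow a list, the first is the adjusted p at the preset correlation and the second the adjusted p with an estimated correlation. All list calls that held with an estimated correlation are reported, and part of those that did not. Calls among list members were also adjusted over the list alone. The lists reported are those of interferon response, cholesterol synthesis, extracellular matrix, contractile genes, chemokines and NF-kB targets, mitosis, DNA replication, hypoxia and glycolysis, Hox genes, genes linked to HMGN proteins, beta cell identity, and markers of macrophages, fibroblasts, epithelium and other endocrine cells.

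Overlap between pools with the same controls was set against 1000 simulated sets of unchanged groups. The share of called genes among the 50 tested genes on each side of a targeted gene was compared with all other genes by Fisher's exact test, two-sided. Stretches of 50 consecutive genes were compared with 1000 shuffles of gene order, a test added after seeing the data.

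The procedure was tested on simulated data with 200 changed genes. Each gene was drawn independently around its mean with its fitted spread. Correlation between genes and differences between cultures or pools were not simulated, so the shares of false calls do not cover them. In the simulated HMGN1 knock out comparison of 13674 genes, 86.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold were called, and 3.1% of calls were false. In the simulated HMGN1 comparison in SV40 MEFs (13469 genes) the shares were 88.1%, 100% and 100%, with 3% false. In that in MIN6 cells (13179 genes) they were 94%, 98.5% and 100%, with 2% false.

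Alternatives were no filter, every probe set on its own, quantile normalization again, a replicate block, only the compared groups in the fit and leaving out each array. Added after seeing the data were the share of male cells as a covariate in primary MEFs, the Actb difference between 3' and 5' probe sets as a covariate in SV40 MEFs (also without each array of the compared groups), and leaving out 1 array of each swap group. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under python 3.11.15.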

Results

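RNA levels were measured on 51 Affymetrix Mouse Genome arrays in 17 groups of 3. The HMGN proteins are small nuclear proteins that bind nucleosomes, and the series asks how losing or adding single members changes transcription. Primary mouse embryonic fibroblasts (MEFs) gave 18 arrays, with knock outs of HMGN1, HMGN3 or HMGN5 and a wild-type (WT) group for each. SV40-transformed MEFs gave 24 arrays. They received an empty vector, a construct labelled as overexpression (OE) of HMGN1, HMGN2, HMGN3a, HMGN5 or HMGN5SE, or an HMGN1 construct labelled N2swap or N3swap. The labels do not say which part was exchanged in the swaps or what SE stands for. MIN6 cells, a mouse insulinoma line of beta-cell character, gave 9 arrays with an empty vector, HMGN1 or HMGN3a. The median intensity per array was 5.47 to 5.93 in primary MEFs, 18.7 to 19.6 in SV40 MEFs and 55.5 to 57.6 in MIN6 cells, so levels were compared within a cell type only. The labels do not say whether the 3 replicates of a group are separate cultures or animals. The median standard deviation (SD) of a gene within a group was 0.066 to 0.126 on the log2 scale, and 3 arrays per group limit the precision. Changes below are log2 differences with their standard error, n = 3 arrays per group. Where the mean of 1 group lay below the level of the filter for dim probe sets (log2 1.99 in primary MEFs, 3.63 in SV40 MEFs and 5.13 in MIN6 cells), that level served as a floor, chosen after seeing the data, and the difference is given as a bound ("at least").

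The targeted genes were read first, as a check of the knock out labels. In the HMGN1 knock out, 3 of the 4 Hmgn1 probe sets fell, by -0.89 ± 0.06, -0.67 ± 0.06 and -0.89 ± 0.06, and the dim remaining one changed by 0.15 ± 0.11. The 3 kept 0.539 to 0.63 of the WT signal, so absence of the protein is taken from the label. The probe set shared by Hmgn2 and its pseudogenes was lower than in HMGN1 WT (-0.64 ± 0.11, limma adjusted p = 0.034 over all probe sets), with a mean of 8.96 against 9.6, where HMGN3 WT had 8.83 and HMGN5 WT 9.02, so it is HMGN1 WT that stands apart. Both Hmgn3 probe sets fell in the HMGN3 knock out, by -1.30 ± 0.08 and -1.46 ± 0.10. The single Hmgn5 probe set went the other way in the arrays labelled HMGN5 knock out: it rose by 0.72 ± 0.12, from a mean of 4.97 to 5.69, and was not called with the share of male cells as a covariate (0.62, adjusted p = 0.121), a choice made after seeing the data. The labels do not say which part of any gene was deleted, so a probe outside that part checks nothing.

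**Figure D1:**
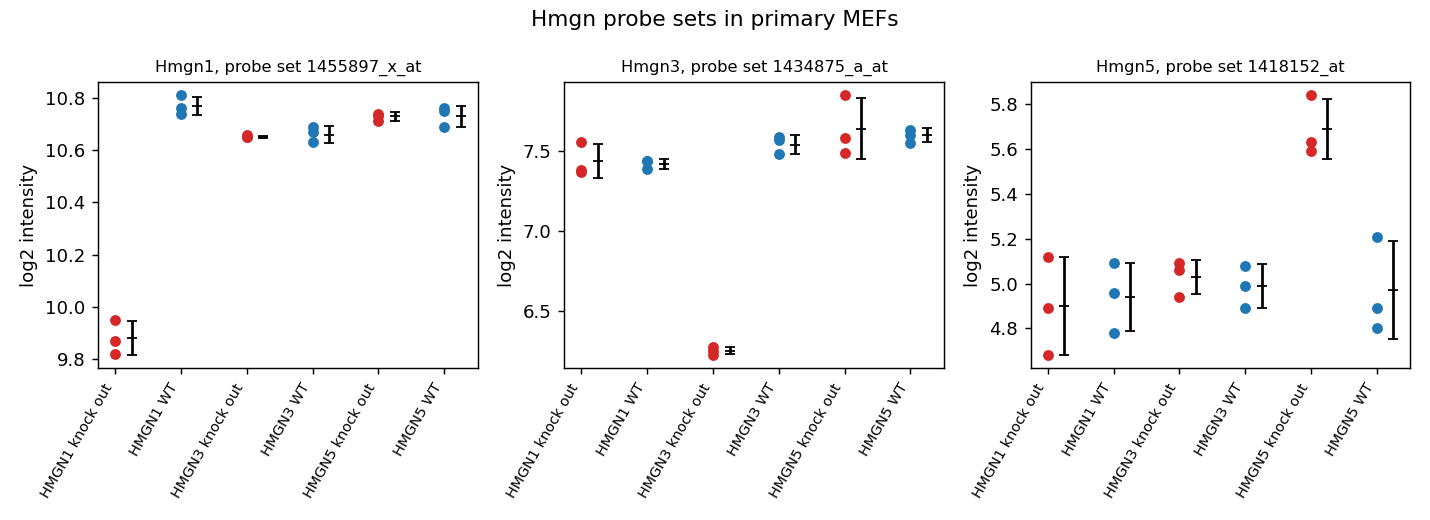
Log2 intensity of the Hmgn1, Hmgn3 and Hmgn5 probe sets in each primary MEF array (points, knock out red and WT blue) with the group mean and SD (bars, n = 3). Hmgn1 and Hmgn3 were lower in their own knock outs, and Hmgn5 was higher in the arrays labelled HMGN5 knock out (5.69 against 4.97).

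The arrays labelled HMGN1 knock out had 48 genes lower and 12 higher than their WT group, of 13674 tested. Trim13, a RING-type ubiquitin ligase, fell most (-2.26 ± 0.15), followed by Tubb3, a beta-tubulin (-1.07 ± 0.08), and Slco4a1, an organic anion transporter (-1.03 ± 0.20). Of 24 DNA replication genes, 5 were lower and 0 higher, and 22 were lower when adjusted over the list alone. The list's camera call (adjusted p = 9.73e-20) was lost with an estimated correlation (adjusted p = 0.415). The lower genes include the polymerase subunit Pola1 (-0.60 ± 0.11) and the helicase subunits Mcm7 (-0.44 ± 0.08), Mcm6 (-0.42 ± 0.05) and Mcm2 (-0.40 ± 0.08). The 24 mitosis genes had a median change of -0.52. None of them was called over all genes (0), and 23 were lower when adjusted over the list alone. Camera called this list too (adjusted p = 1.39e-15), and the call was lost with an estimated correlation (adjusted p = 0.415). Outside the lists, the exonuclease Exo1 (-0.66 ± 0.12) and the spindle protein Dlgap5 (-0.64 ± 0.09) also fell. Hspa1b, a heat shock gene linked to HMGN1 in earlier studies, fell by -0.39 ± 0.07. Trnp1, a nuclear protein of neural progenitors, rose by 1.16 ± 0.18, Fam124a by 0.78 ± 0.12, the secreted peroxidase Gpx3 by 0.70 ± 0.12 and the hypoxia-responsive gene Ndrg1 by 0.48 ± 0.10. Cholesterol synthesis genes had a median of -0.16 with 0 of 18 called (camera adjusted p = 0.000913, adjusted p = 0.477 with an estimated correlation).

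The groups behind this comparison differed in sex-linked RNA. All 3 HMGN1 WT arrays had Xist levels of 8.56 to 8.63 and Eif2s3y, a Y-linked gene, at 1.31 to 1.41. Among the knock out arrays, replicate 1 had Xist at 3.14 and Eif2s3y at 5.85, replicate 2 had 8.61 and 1.28, and replicate 3 had both (7.4 and 5.23). An unadjusted p below 0.05 was reached by 2121 genes. Without HMGN1 WT replicate 1, 2 or 3 the count was 37, 36 or 18, with only the compared groups in the fit it was 7, and quantile normalization moved the share of higher calls from 20% (12 of 60) to 43.5% (40 of 92). With the share of male cells as a covariate, chosen after seeing the data, 82 genes were called and 35 of the 60 were among them in the same direction. Of the genes named here, Mcm2 (-0.40) and Gpx3 (0.52) were not.

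In the HMGN3 knock out, interferon response genes rose together. Of 29 measured, 23 were higher and 0 lower, and 28 were higher when adjusted over the list alone. The list's median change was 0.90, and its camera call held with an estimated correlation (adjusted p = 1.05e-63 and 0.00264). Between WT groups its median was 1.32 (HMGN3 against HMGN1), 1.35 (HMGN5 against HMGN1) and 0.002 (HMGN5 against HMGN3). Larger differences thus also occurred without a knock out, so a difference between cultures is not excluded. Ifit3, which binds viral RNA complexes, rose by 1.88 ± 0.33, the immunity-related GTPase Iigp1 by 1.76 ± 0.32, Gbp3 by 1.71 ± 0.24 and Oasl2 by 1.61 ± 0.20. The deubiquitinase-like Usp18 rose by 1.54 ± 0.27 and the transcription factor Irf7 by 1.19 ± 0.15. Tmem178 rose by at least 0.92. Azi2, an adaptor of TBK1 signalling, rose by 1.11 ± 0.07 and lies on chromosome 9 as Hmgn3 does. On that chromosome 4 of 775 other genes were called (0.52%), against 75 of 12873 elsewhere (0.58%). Whether DNA linked to Hmgn3 accounts for the rise of Azi2 was not tested. Macrophage and leukocyte markers had 0 of 18 members called and a median of 0.07 (camera adjusted p = 0.69). Among genes that fell were the carbonic anhydrase-related Car8 (-0.96 ± 0.15), the chromatin organizer Satb1 (-0.74 ± 0.14), the nuclear receptor Nr4a2 (-0.58 ± 0.10) and the Wnt receptor Fzd6 (-0.56 ± 0.07). In all, 66 genes were higher and 14 lower, and 1158 had an unadjusted p below 0.05. The count was 34 or 31 without HMGN3 knock out replicate 2 or 3, 42, 39 or 43 without HMGN3 WT replicate 1, 2 or 3, and 141 with only the compared groups in the fit.

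The arrays labelled HMGN5 knock out differed least from their WT group, with 5 genes higher and 5 lower. Besides Hmgn5 itself, Mpp1, a membrane scaffold protein, rose by 0.93 ± 0.08, Dkc1, the pseudouridine synthase dyskerin, by 0.78 ± 0.05, the netrin Ntn4 by 0.55 ± 0.09 and the complex I gene Ndufa12 by 0.29 ± 0.05. Mpp1 and Dkc1, the largest rises, lie on chromosome X as Hmgn5 does, in groups that differ in sex-linked RNA (2 of 414 other genes called there, 7 of 13234 elsewhere, exact p = 0.0287, adjusted p = 0.0597 over the 3 knock outs). Cd200, an immune-inhibitory surface protein, fell by -1.11 ± 0.16, Zfp804a by at least 0.51, the cytokine Il11 by -0.64 ± 0.08, Enpp4 by -0.58 ± 0.09 and the TGF-beta receptor Tgfbr1 by -0.37 ± 0.06. Mitosis genes had a median of 0.20 with 0 of 24 called (camera adjusted p = 1.09e-06, adjusted p = 0.818 with an estimated correlation), and hypoxia and glycolysis genes a median of 0.10 with 0 of 22 called and 2 higher when adjusted over the list alone (4.94e-05, adjusted p = 0.818 with an estimated correlation). The HMGN5 WT arrays had Xist at 2.4 to 2.78, and the arrays labelled knock out were mixed, at 8.72, 2.6 and 7.69. With the share of male cells as a covariate, chosen after seeing the data, 14 genes were called, and of the 10 only Mpp1, Dkc1, Cd200 and Il11 (4) were among them. With all 18 primary MEF arrays in the fit, 764 genes had an unadjusted p below 0.05. The limma count of called genes was 0 when only the compared groups entered the fit. It was 21, 23 or 5 without replicate 1, 2 or 3 of the labelled knock out and 18 without HMGN5 WT replicate 1.

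The knock out effects were also tested against each other. The HMGN1 and HMGN3 effects differed for 69 genes, 16 of them more positive in the HMGN1 knock out. Usp18 (-2.05 ± 0.38), Gbp3 (-2.02 ± 0.34), Rtp4 (-1.73 ± 0.34) and Oasl2 (-1.67 ± 0.29), all interferon-induced, were among the most negative, with Trim13 (-2.17 ± 0.21). For the 4 interferon-induced genes most of the difference was the rise in the HMGN3 knock out. They changed by -0.52, -0.30, -0.44 and -0.06 in the HMGN1 knock out. Their levels were 2.73, 3.25, 3.29 and 2.22 in HMGN1 WT, nearer the floor than the 6.75, 4.32, 6.77 and 4.85 in HMGN3 WT. The HMGN3 and HMGN5 effects differed for 58 genes, with Oasl2 at 1.84 ± 0.29, the transcription factor Zic1 at 1.83 ± 0.38 and Irf7 at 1.16 ± 0.21. The homeobox gene Hoxa11 (-1.27 ± 0.22) and the chemokine gene Ppbp were on the other side, Ppbp with 1 of its 4 groups below the floor. The HMGN1 and HMGN5 effects differed for 22 genes, among them Trim13 (-2.23 ± 0.21), Tubb3 (-0.98 ± 0.12) and Il11 (0.69 ± 0.11). With the share of male cells as a covariate the counts were 235, 73 and 51 for HMGN1 with HMGN3, HMGN1 with HMGN5 and HMGN3 with HMGN5, sharing 66 of the 69, 12 of the 22 and 38 of the 58 calls, and Il11 was lost from the second. Where HMGN5 enters, the direction rests on arrays whose Hmgn5 probe set went against their label. The count of 69 was 28 without HMGN1 WT replicate 3, 44 or 26 without HMGN3 knock out replicate 2 or 3, and 32 or 38 without HMGN3 WT replicate 2 or 3. The count of 22 was 12 without HMGN1 WT replicate 3, 57 or 10 without labelled HMGN5 knock out replicate 1 or 3, and 144 or 12 without HMGN5 WT replicate 1 or 3. The count of 58 was 20 or 16 without HMGN3 knock out replicate 2 or 3, 19, 22 or 31 without HMGN3 WT replicate 1, 2 or 3, 116 or 17 without labelled HMGN5 knock out replicate 2 or 3, and 88, 26 or 19 without HMGN5 WT replicate 1, 2 or 3.

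The WT groups were compared with one another to show how far cultures of different sets differ. HMGN3 WT against HMGN1 WT gave 4306 genes (1519 higher), HMGN5 WT against HMGN1 WT 1602 (644 higher) and HMGN5 WT against HMGN3 WT 2355 (1354 higher). Interferon response genes were higher in HMGN3 WT than in HMGN1 WT in 28 of 29 cases (median 1.32, camera adjusted p = 1.49e-25, adjusted p = 0.103 with an estimated correlation). In HMGN5 WT against HMGN1 WT, 22 of 29 were higher (median 1.35, 1.68e-35 and 0.0315). Usp18 differed by 4.02 ± 0.27 and 4.19 ± 0.27 in these contrasts and Cd200 by 3.99 ± 0.16 and 3.83 ± 0.16. Macrophage and leukocyte markers were higher in HMGN3 WT than in HMGN1 WT for 7 of 18 (camera adjusted p = 7.06e-05, adjusted p = 0.613 with an estimated correlation). Between HMGN5 WT and HMGN3 WT, the patterning genes Rarb (2.42 ± 0.12) and Hoxa5 (2.35 ± 0.17) were higher, and Ang, a secreted ribonuclease (by at least 4.65), and the Wnt-pathway receptor Lgr5 (-2.91 ± 0.26) lower. Another Lgr5 probe set changed by -0.02 and was not called. Xist differed by -5.91 ± 1.28 and -5.95 ± 1.28 in the contrasts against HMGN1 WT and Eif2s3y was higher by at least 4.38 and 4.51. With the share of male cells as a covariate, chosen after seeing the data, the counts against HMGN1 WT were 2396 and 552, of which 1900 and 341 were shared with the 4306 and 1602. The 1602 fell to 988, 904 or 927 without HMGN5 WT replicate 2, HMGN5 WT replicate 3 or HMGN1 WT replicate 3.

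**Figure D2:**
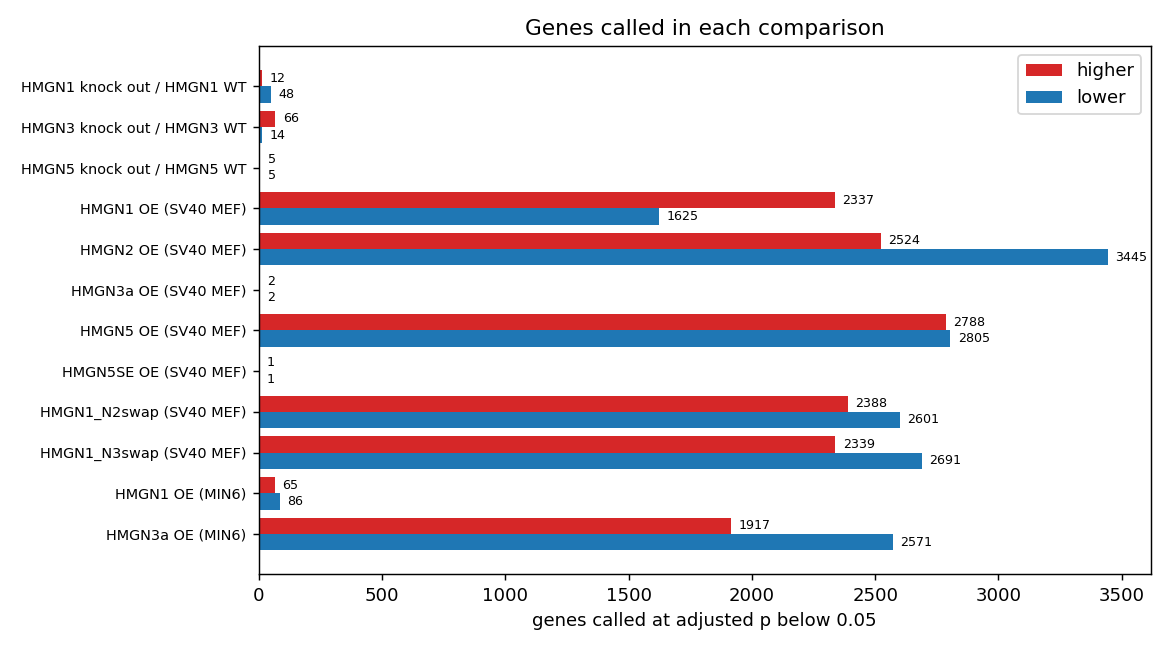
Number of genes called higher (red) and lower (blue) at an adjusted p below 0.05 in each of the 12 knock out and construct comparisons, 3 arrays against 3. Counts run from 2 genes with HMGN5SE to 5969 with HMGN2 in SV40 MEFs.

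The construct groups are transduced pools, and the labels do not say whether the 3 arrays of a group come from separate transductions, so the values below are differences between pools, not shown to come from the protein. In SV40 MEFs carrying HMGN1, interferon response genes rose strongly. Of 29 measured, 28 were higher and 0 lower, also when adjusted over the list alone, with a median change of 2.44 (camera adjusted p = 5.86e-45, adjusted p = 0.00891 with an estimated correlation). Usp18 rose by 5.70 ± 0.18, Irf7 by 4.66 ± 0.14 and the oligoadenylate synthetase Oas1a by 4.63 ± 0.10. All 18 cholesterol synthesis genes rose (median 0.88, 2.7e-20 and 0.0155), including Fdps (1.38 ± 0.11), Cyp51 (1.05 ± 0.08) and the SREBP regulator Insig1 (1.05 ± 0.12). Of 24 mitosis genes, 20 rose, 21 when adjusted over the list alone (median 0.31, 4.23e-10 and 0.0159), such as the kinase Plk1 (0.50 ± 0.06). Contractile genes and targets of SRF or YAP fell in 10 of 19 cases (median -0.25, 9.07e-07 and 0.00508), with the smooth muscle protein Tagln at -1.92 ± 0.08 and the matricellular Ccn2 at -0.95 ± 0.09. Of 9 genes linked to HMGN proteins in earlier studies, 6 fell and 1 rose (median -0.53, 0.0122 and 0.0411): the heat shock gene Hspa1b changed by -0.57 ± 0.09, the cartilage regulator Sox9 by -0.64 ± 0.08 and Fosl1 by -0.56 ± 0.07. The neuronal tubulins Tubb2b (-1.93 ± 0.15) and Tubb3 (-1.19 ± 0.14) and the prostaglandin synthase Ptgs2 (-1.49 ± 0.10) also fell, the last among 6 of 17 chemokine and NF-kB genes that did, with 2 higher (0.00752 and 0.0259). In all 2337 genes were higher and 1625 lower of 13469, and 486 changed at least 1.5-fold. Quantile normalization turned the share of higher calls from 59% to 48.9% (1856 of 3798).

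With HMGN2 more genes were called, 2524 higher and 3445 lower, with 1156 at 1.5-fold or more. The cadherin Cdh11 rose by 4.79 ± 0.12, the retinoic acid-binding Crabp1 by 4.36 ± 0.16 and the collagen-crosslinking enzyme Lox by at least 4.06. Extracellular matrix genes rose in 24 of 32 cases, 25 when adjusted over the list alone, and fell in 2 (median 0.57, camera adjusted p = 1.13e-14, adjusted p = 0.00708 with an estimated correlation), with Col3a1 at 2.99 ± 0.12 and Col1a2 at 2.22 ± 0.08. Interferon response genes rose in 29 of 29 cases (median 2.59, 5.21e-37 and 0.00708, Usp18 4.58 ± 0.18) and cholesterol synthesis genes in 18 of 18 (median 1.26, 4.2e-23 and 0.0067, Cyp51 2.11 ± 0.08). Contractile genes, which fell with HMGN1, rose in 12 of 19 cases with 1 lower (median 0.32, 6.04e-07 and 0.00501, Tagln 2.05 ± 0.08, Acta2 2.75 ± 0.10). Fibroblast markers rose in 7 of 11 cases (Thy1 2.70 ± 0.13, 1.52e-07 and 0.00501) and chemokine and NF-kB genes in 9 of 17, with 2 lower (0.000335 and 0.00614). Hypoxia and glycolysis genes rose in 19 of 23 cases with 1 lower, a call lost with an estimated correlation (adjusted p = 2.13e-09 and 0.0628). The Id genes, inhibitors of basic helix-loop-helix factors, fell: Id2 by -2.69 ± 0.12, Id1 by -2.34 ± 0.10, Id3 by -1.57 ± 0.09 and Id4 by -1.57 ± 0.14. Sbsn, a keratinocyte protein, fell by -2.88 ± 0.12. Hox genes were lower in 12 of 22 cases, 14 when adjusted over the list alone (median -0.30, adjusted p = 0.00469 and, with an estimated correlation, adjusted p = 0.0554).

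The HMGN5 pool had the largest single changes against the vector, with 2788 higher and 2805 lower genes, 1548 of them at least 1.5-fold. The matrix protein Fbln2 rose by 6.00 ± 0.11, the imprinted Dlk1 by 5.96 ± 0.12, Lox by at least 5.66, the basement membrane protein Nid1 by 5.50 ± 0.13 and the transcription factor Sox2 by at least 2.54. Extracellular matrix genes rose in 27 of 32 cases and fell in 2 (median 1.22, camera adjusted p = 5.18e-17, adjusted p = 0.00984 with an estimated correlation), and contractile genes rose in 15 of 19 with 1 lower (median 0.49, 6.29e-06 and 0.00984, Acta2 3.57 ± 0.10). Hox genes rose in 12 of 22 cases and fell in 0 (median 0.26, 3.46e-05 and 0.0119), with Hoxc6 at 3.00 ± 0.11 and Hoxb6 at 2.91 ± 0.10. Cholesterol synthesis genes rose in 17 of 18 cases with 1 lower, a call lost with an estimated correlation (2.59e-10 and adjusted p = 0.0973). Of the interferon response genes, 20 of 29 fell and 2 rose (Oasl2 by at least 2.99, Ifit1 -3.78 ± 0.13). That list had a median of -0.82, and its camera call (adjusted p = 1.36e-09) was lost with an estimated correlation (adjusted p = 0.253). The developmental transcription factors Tbx20 (by at least 3.92) and Alx1 (by at least 3.34) fell. Fibroblast markers rose in 8 of 11 cases with 1 lower (4.96e-05 and 0.018). The Hmgn5 probe set fell by -0.93 ± 0.09, and 3 of the 4 Hmgn1 probe sets rose by 0.37 to 0.45.

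The HMGN3a and HMGN5SE pools of SV40 MEFs had few calls. With HMGN3a, 4 genes were called: the histone gene H3f3b (0.74 ± 0.13) and the early response gene Egr1 (0.45 ± 0.07) were higher, and the oncogene Mycn (-0.51 ± 0.07) and the linker histone Hils1 (-0.47 ± 0.08) lower. With HMGN5SE, H3f3b rose by 1.05 ± 0.13 and Mycn fell by -1.58 ± 0.07. Of 3 Mycn probe sets only this 1 moved: the other 2 changed by 0.03 and -0.01 with HMGN3a and by 0.01 and -0.09 with HMGN5SE, and were not called. Unadjusted p-values below 0.05 numbered 1466 and 704. The count with HMGN3a was 2 without HMGN3a replicate 3, 2 or 1 without empty vector replicate 2 or 3, and in limma 0 with only the compared groups in the fit (1746 at an unadjusted p below 0.05). With HMGN3a, camera called the interferon response (median 0.14, 0 of 29 members called, adjusted p = 0.0405) and cholesterol synthesis lists (median 0.12, 0 of 18 called, adjusted p = 0.00286), both lost with an estimated correlation (adjusted p = 0.762 for each). With HMGN5SE, cholesterol synthesis genes had a median of -0.09 (0 of 18 called, adjusted p = 0.0217, lost at adjusted p = 0.719 with an estimated correlation). Contractile genes shifted slightly with HMGN5SE (median 0.10, 0 of 19 called, 1 when adjusted over the list alone, camera adjusted p = 0.000184 and 0.022 with an estimated correlation). Tested directly, HMGN5 and HMGN5SE differed for 5652 genes, 2668 higher with HMGN5. Matrix genes were higher in 24 of 32 cases and lower in 2 (median 1.15, adjusted p = 6.17e-16, 0.0149 with an estimated correlation). The contractile, Hox and fibroblast marker lists were also higher with HMGN5 (14 of 19, 11 of 22 and 8 of 11 called higher and 1, 2 and 0 lower, adjusted p = 0.0149, 0.0177 and 0.0149 with an estimated correlation). Fbln2 differed by 6.20 ± 0.11 and Tbx20 was lower with HMGN5 by at least 4.03.

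The Hmgn probe sets were also read in the construct groups. With HMGN1 in SV40 MEFs the 4 Hmgn1 probe sets changed by -0.08 to 0.02, and in MIN6 cells by -0.05 to -0.01. The Hmgn2 probe set changed by 0.11 ± 0.08 with HMGN2. In MIN6 cells with HMGN3a, Hmgn3 probe sets rose by 0.23 ± 0.06 and 0.26 ± 0.07, and in SV40 MEFs with HMGN3a they changed by -0.23 ± 0.08 and -0.02 ± 0.07 (not called). Among the other members, both Hmgn3 probe sets rose with HMGN2 (0.39 ± 0.07 and 0.29 ± 0.08), N2swap (0.43 ± 0.07 and 0.38 ± 0.08) and N3swap (0.52 ± 0.07 and 0.35 ± 0.08), and the Hmgn2 probe set rose with HMGN5 (0.39 ± 0.08). The Hmgn5 probe set fell with HMGN1 (-0.29 ± 0.09) and HMGN2 (-0.26 ± 0.09), and 1 of the 4 Hmgn1 probe sets rose with HMGN2 (0.18 ± 0.06) and N3swap (0.17 ± 0.06). Whether these probes cover the introduced sequences is not stated, so the values neither show nor exclude expression of the constructs.

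The 2 HMGN1 swap constructs were each set against the empty vector. With N2swap 2388 genes were higher and 2601 lower, and with N3swap 2339 were higher and 2691 lower. In both, Crabp1 (5.68 ± 0.16 and 5.82 ± 0.16), the sphingosine phosphate receptor S1pr3 (by at least 3.53 and 3.26), the surface protein Cd34 (4.09 ± 0.18 and 3.83 ± 0.18) and Nid1 (4.01 ± 0.13 and 3.73 ± 0.13) rose. The water channel Aqp1 (-2.42 ± 0.09 and -2.74 ± 0.09), the necroptosis kinase Ripk3 (-2.40 ± 0.11 and -2.44 ± 0.11) and Sbsn (-2.77 ± 0.12 and -2.53 ± 0.12) fell. The heat shock gene Hspa1a (-1.20 ± 0.13 and -1.28 ± 0.13) and the small heat shock protein gene Cryab (-1.55 ± 0.12 and -1.61 ± 0.12) were lower. Matrix genes rose in 14 and 15 of 32 cases with 1 lower in each (camera adjusted p = 4.46e-05 and 5.39e-05), calls lost with an estimated correlation (adjusted p = 0.262 and 0.296). Xist also set pools apart, at 6.88 to 7.78 in the swap arrays and 6.16 to 6.55 with HMGN2, against 4.7 to 4.91 with the vector, and at 4.08 to 4.8 in the other pools. RNA of the swap groups was more 3'-biased in the Actb control, with a difference of 0.64 ± 0.22 and 0.61 ± 0.15 (SD) against 0.26 ± 0.03 with the vector. The Gapdh control gave 0.19 ± 0.17 and 0.22 ± 0.13 against 0.16 ± 0.01. With the Actb difference as a covariate, chosen after seeing the data, 3628 and 3811 genes were called, and 2715 (54.4%) and 2898 (57.6%) of the calls without it were among them in the same direction, down to 21.3% without N2swap replicate 3 and 43.1% without N3swap replicate 1. N2swap replicate 3 and N3swap replicate 1 were nearer each other (median absolute log2 difference 0.091) than the nearest array of their own groups (0.161 and 0.143), and N2swap replicate 2 was nearer an N3swap array (0.107) than its own group (0.113). The arrays thus did not separate by construct, and neither a wrong label nor a shared batch was excluded, which bears on all values of both swaps. Without both arrays, a choice made after seeing the data, 5491 and 5395 genes were called.

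The direct contrasts set each swap against HMGN1 and against HMGN2 (N2swap) or HMGN3a (N3swap). That N2 and N3 refer to these proteins is an assumption from the labels. With N2swap 28 of 29 interferon genes were lower than with HMGN1 (median -2.77, camera adjusted p = 4.03e-29, 0.0351 with an estimated correlation), and with N3swap also 28 (median -2.57, 1.1e-27 and 0.0422). Usp18 differed by -5.82 ± 0.18 and -5.78 ± 0.18. All 18 cholesterol synthesis genes were lower in both (adjusted p = 1.18e-07 and 4.37e-09), calls lost with an estimated correlation (adjusted p = 0.157 and 0.161). Contractile genes were higher in 13 and 14 of 19 cases (adjusted p = 1.76e-06 and 1.49e-06, 0.00639 and 0.00546 with an estimated correlation), with Tagln at 2.04 ± 0.08 and 2.30 ± 0.08, and so were chemokine and NF-kB genes in 8 and 8 of 17 with 1 lower in each (0.00704 and 0.0137 with an estimated correlation). Against HMGN2, N2swap was lower in 29 of 29 interferon genes (median -2.52, 3.91e-32 and 0.0278) and 18 of 18 cholesterol synthesis genes (median -1.07, 3.12e-16 and 0.0278), in 11 of 19 contractile genes with 2 higher and in 6 of 11 fibroblast markers (0.0278 for each with an estimated correlation). Lox differed by -2.86 ± 0.14 and Id2 by 2.47 ± 0.12. N3swap against HMGN3a gave 5722 genes, led by Crabp1 (5.82 ± 0.16) and Aqp1 (-2.76 ± 0.09). The direct contrasts called 6205 genes (2688 higher) for N2swap against HMGN1, 6857 (3064 higher) for N3swap against HMGN1 and 6762 (3731 higher) for N2swap against HMGN2. With the Actb covariate N2swap against HMGN2 gave 3698, of which 2854 were shared with the 6762 in the same direction, where the Actb difference was 0.64 and 0.09 in these groups. The other contrasts shared 4034 of the 6205, 4769 of the 6857 and 3075 of the 5722.

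**Figure D3:**
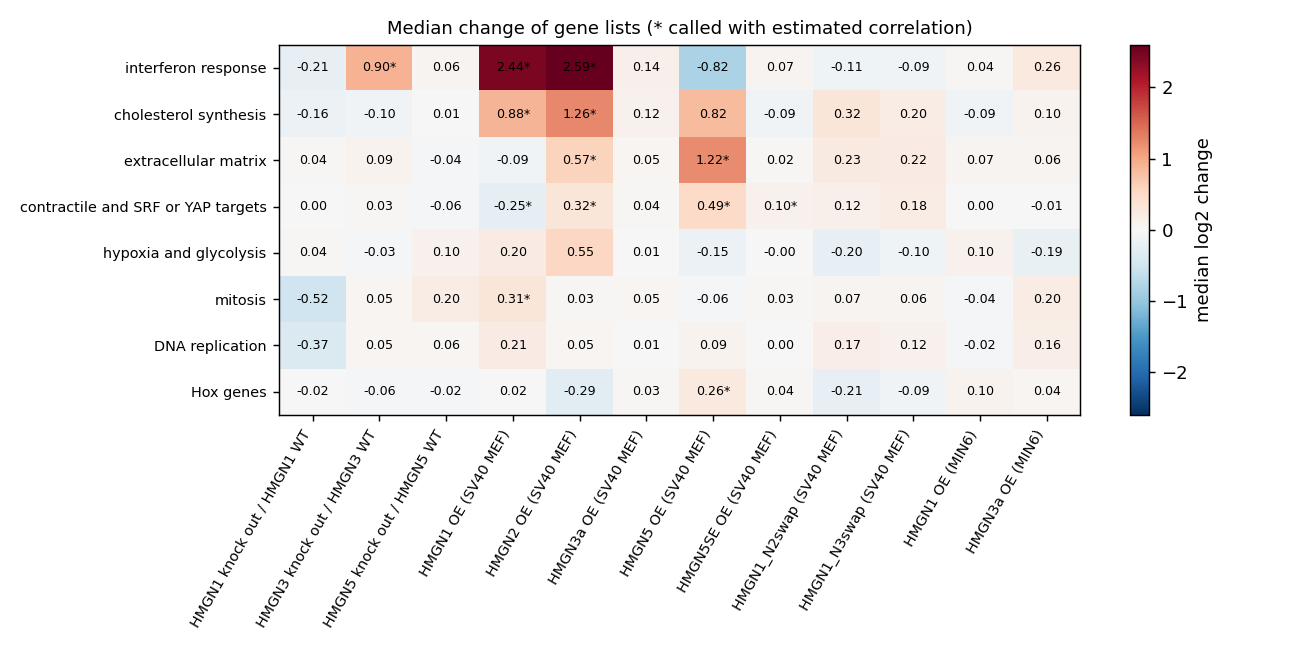
Median log2 change of 8 gene lists (rows) in each of the 12 comparisons (columns), 3 arrays against 3, with an asterisk where the camera call held with an estimated correlation. Interferon response medians reach 2.44 with HMGN1 and 2.59 with HMGN2 in SV40 MEFs and stand at -0.82 with HMGN5.

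Calls overlapped between pools that share the vector arrays. HMGN1 and HMGN2 shared 971 higher and 885 lower genes, where independent lists would share 437.9 and 415.6, and 275 and 201 genes were called in opposite directions. Their changes had a covariance across genes of 0.062, against 0.00478 for simulated unchanged groups. They correlated at 0.45. The 0.50 of simulated unchanged groups follows from the shared controls alone, so it is no reference for this correlation. HMGN2 and HMGN5 shared 1080 higher and 1233 lower (522.5 and 717.4 by independence, covariance 0.0612), with 411 and 409 in opposite directions. HMGN1 and HMGN5 shared 811 and 612 (483.7 and 338.4), with 458 and 278 in opposite directions and a covariance of 0.00295. The swaps shared 1849 and 2154 (414.7 and 519.7), called no gene in opposite directions (0) and had a covariance of 0.108, from arrays that did not separate by construct. The 3 vector arrays are too few to split, so part of the excess may come from them. The covariance of HMGN1 and HMGN5 lay below the simulated one. Genes with the same direction in at least 3 pools included Sbsn, lower in 5 pools (median -2.77), Lox, the chemokine-scavenging receptor Ackr3 and the semaphorin Sema5a (2.72), higher in 4, and Ripk3 (-2.42) and Snhg14, lower in 4. Lox, Ackr3 and Snhg14 were below the floor on 1 side, so no size is given.

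In MIN6 cells with HMGN1, 65 genes were higher and 86 lower of 13179. The X-linked Tex13b rose by 1.84 ± 0.14, the hedgehog-binding Hhip by at least 0.59, the transcription factor Maf by 1.04 ± 0.08 and the pyruvate dehydrogenase kinase Pdk1 by 0.54 ± 0.09. The S6 kinase Rps6kb2 fell by -1.46 ± 0.07. Of 22 beta-cell identity genes, 2 fell and 0 rose: Slc2a2, the beta-cell glucose transporter GLUT2 (-0.81 ± 0.10), and the peptide hormone Ucn3 (-0.65 ± 0.11). The list itself was not called (median -0.01, camera adjusted p = 0.289). Hypoxia and glycolysis genes had a median of 0.10 with 1 of 23 called (3.45e-05, adjusted p = 0.615 with an estimated correlation). The count was 39, 51 or 50 without HMGN1 replicate 1, 2 or 3 and 77, 70 or 91 without empty vector replicate 1, 2 or 3.

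With HMGN3a many more genes were called in MIN6 cells, 1917 higher and 2571 lower and 869 at 1.5-fold or more. The islet hormone somatostatin (Sst) fell by -5.04 ± 0.09, the neuritin Nrn1 by at least 3.88, the neuronal Stmn2 by at least 3.66 and the vesicular glutamate transporter Slc17a6 by at least 2.32. Tex13b rose by 3.76 ± 0.14, Maf by 2.92 ± 0.08 and the mitochondrial RNA-binding Lrpprc by 2.40 ± 0.06. Among 22 beta-cell identity genes, 5 rose and 2 fell, with Slc2a2 at -1.26 ± 0.10, the channel Trpm5 at 0.83 ± 0.07 and Ucn3 at 0.77 ± 0.11 (list median 0.03, camera adjusted p = 0.542). Of 7 markers of other endocrine cells, 1 rose and 3 fell (Ppy 1.12 ± 0.13, Gcg -0.44 ± 0.06). Epithelial markers rose in 8 of 13 cases with 1 lower (Cldn7 2.03 ± 0.09, Epcam 1.07 ± 0.09, adjusted p = 0.00152, adjusted p = 0.325 with an estimated correlation). Mitosis and DNA replication genes rose in 11 of 24 and 11 of 25 cases, with 2 and 1 lower (0.00376 and 0.00152, adjusted p = 0.655 for both with an estimated correlation). Hypoxia and glycolysis genes fell in 11 of 23 cases with 1 higher (0.00446, adjusted p = 0.675 with an estimated correlation), with Egln3 at -1.39 ± 0.13 and P4ha2 at -1.38 ± 0.09. HMGN1 and HMGN3a shared 36 higher and 54 lower genes in MIN6 cells (9.5 and 16.8 by independence), with 14 and 16 in opposite directions and a covariance of 0.0125 against 0.00356 in simulated unchanged groups.

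Neighbouring genes were read together as a measured fact about the pools, with gene order from the GRCm38.p6 table. In the HMGN5 pool of SV40 MEFs, 36 of the 50 tested genes between 4930548G14Rik and Phf20l1 on chromosome 15 were called lower, and the median of this stretch was -0.85, where gene order shuffled 1000 times gave medians of at most 0.232 in size. The same stretch had medians of -0.34 with N2swap and -0.29 with N3swap. In the HMGN3a pool of MIN6 cells, 377 of 636 tested genes of chromosome 10 were called, 364 of them lower (median -0.28), and 397 of the 424 called genes of chromosome 4 were lower. DNA was not measured.

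**Figure D4:**
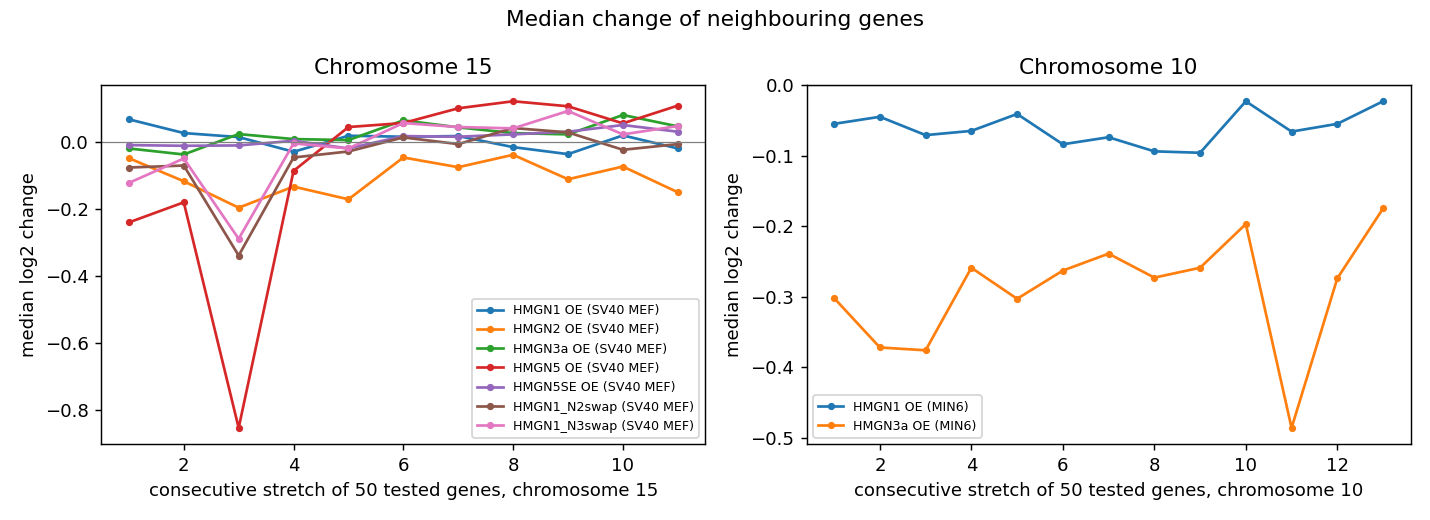
Median log2 change of consecutive stretches of 50 tested genes (lines, 1 per pool, 3 arrays against 3) along chromosome 15 in the 7 SV40 MEF pools and chromosome 10 in the 2 MIN6 pools. The HMGN5 pool has its lowest stretch on chromosome 15 at -0.85.

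The difference with the same construct was compared between the 2 lines. The HMGN1 effects differed for 2902 genes of 16019, with Usp18 at 5.80 ± 0.23 and Irf7 (1 MIN6 group below the floor) more positive in SV40 MEFs, and Tubb2b at -2.67 ± 0.23 and Maf at -2.19 ± 0.16 more negative. The HMGN3a effects differed for 2821 genes, with Nrn1 (below the floor with HMGN3a in MIN6 cells) more positive, Sst at 4.94 ± 0.14, Maf at -3.31 ± 0.16 and Lrpprc at -2.49 ± 0.08. Across genes, the HMGN1 knock out in primary MEFs and HMGN1 in SV40 MEFs correlated at -0.12 over 12677 genes, with 9 shared calls in the same and 17 in the opposite direction. For the HMGN3 knock out and HMGN3a in MIN6 cells the correlation was 0.08, with 22 calls in the same and 15 in the opposite direction. The other pairs gave 0.02 for the HMGN1 knock out and HMGN1 in MIN6 cells (0 same, 1 opposite), 0.04 for the HMGN3 knock out and HMGN3a in SV40 MEFs (0 and 0) and -0.03 for the arrays labelled HMGN5 knock out and HMGN5 in SV40 MEFs (1 and 3).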

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

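The test of genes next to each targeted gene was planned, and the tests of the splits, the male covariate, single arrays, normalization, RNA quality, whole chromosomes and chromosome stretches were chosen only after the result was seen. The genes named next to Hmgn1 were chosen after their values were seen.

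Effects differed between groups in 5 direct tests of the difference. The HMGN1 and HMGN3 knock out effects differed for 69 genes, the highest count of the 100 splits drawn, the highest other being 14, so 1 of 100 splits gave as many. The HMGN1 and HMGN5 effects differed for 22 genes and 2 of 100 splits gave as many, the highest other being 41. The HMGN3 and HMGN5 effects differed for 58 genes and 2 of 100 splits gave as many, the highest other being 113. For HMGN1 in SV40 MEFs and MIN6 cells the count was 2902 (1 of 100, highest other 2897), and for HMGN3a 2821 (2 of 100, highest other 2855). Splits that keep neither contrast gave far lower counts, so chance assignment of single arrays in both contrasts at once is argued against. Splits that keep 1 real contrast and mix the other reached 14, 41, 113, 2897 and 2855 in the same order. Except for the first test, the count thus does not show that both effects are real. A chance difference between whole cultures or pools is not excluded either, since the splits only exchange arrays of the compared groups. WT groups without a knock out differed for 4306, 1602 and 2355 genes. The high counts among the other splits came from splits that keep 1 of the real contrasts whole, and the highest count among splits that keep neither was 0, 3, 0, 4 and 5 in the same order.

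Probe sets with no gene name or several, of which the report reads only that of Hmgn2 and its pseudogenes, were called in 33 cases in primary MEFs, 2653 in SV40 MEFs and 733 in MIN6 cells, of 4058, 4455 and 3814 tested. These are 0.8, 59.6 and 19.2%, against 0.8, 74.3 and 28.3% of the named probe sets.

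Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each. The real count and the highest other were 60 and 3 for the HMGN1 knock out, 80 and 0 for HMGN3, and 10 and 2 for the arrays labelled HMGN5 knock out. In SV40 MEFs they were 3962 and 1 for HMGN1, 5969 and 0 for HMGN2, 4 and 0 for HMGN3a, 5593 and 0 for HMGN5, 2 and 0 for HMGN5SE, 4989 and 1 for N2swap and 5030 and 1 for N3swap. In MIN6 cells they were 151 and 0 for HMGN1 and 4488 and 0 for HMGN3a. The direct contrasts had 5652, 6205, 6857, 6762 and 5722, each with a highest other of 0, and the WT contrasts had 4306 and 0, 1602 and 1, and 2355 and 0.

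Genes next to Hmgn1 were called more often in its knock out. Of the 64 tested neighbours (50 before and 14 after), 5 were called (7.81%), against 54 of 13584 others (0.4%, Fisher's exact test two-sided p = 7.97e-06, adjusted p = 2.39e-05 over the 3 knock outs). Sh3bgr (-0.90 ± 0.10), Urb1 (-0.68 ± 0.14), Cryzl1 (-0.66 ± 0.07) and Ifnar1 (-0.52 ± 0.08) were lower and Pigp (0.32 ± 0.06) higher, so DNA of the stem cell strain linked to the targeted gene may account for these calls, while an effect of HMGN1 on its neighbours stays open and untested. Around Hmgn3 and Hmgn5, 0 of 100 neighbours were called by limma in each (exact p = 1 and p = 1), which decides nothing there. Counted over the whole chromosome the two-sided exact p was 0.0398, 1 and 0.0287 (adjusted 0.0597, 1 and 0.0597), which misses 0.05, with Dkc1 and Mpp1 called on chromosome X for Hmgn5. Azi2 was among the 4 genes called on chromosome 9 for Hmgn3.

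The mean log2 value of the 48 mitosis and DNA replication genes was lower in the HMGN1 knock out by -0.45 ± 0.13 (n = 3 against 3), while the calls of both lists were lost with an estimated correlation (adjusted p = 0.415 for each). With the male index as a covariate the difference was -0.42 ± 0.15, without HMGN1 knock out replicate 1 it was -0.36 ± 0.14, and after quantile normalization again -0.39 ± 0.12. Each stayed above 50 percent of its size by more than its standard error, which argues against the sex of the embryos, that array or the normalization as the whole cause. A difference in growth state between the cultures, from HMGN1 or from the cultures themselves, may remain and was not tested. Single arrays had means of 5.85, 6.11 and 6.06 in the HMGN1 knock out and 6.32, 6.55 and 6.48 in HMGN1 WT. HMGN5 WT arrays had 6.66, 6.03 and 6.36, and HMGN3 WT arrays 6.38, 6.36 and 6.27. Arrays of 1 WT group thus also lay far apart, and 1 WT array lay within the range of the knock out.

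Pools of SV40 MEFs called from 2 to 5969 genes. RNA quality as the whole cause is argued against for HMGN1, HMGN2 and HMGN5 by the Actb covariate, with which at least 85.6% of the calls (HMGN2) were made again in the same direction, and at least 80.4% without any 1 array of the compared groups. For the swaps it stays open: 54.4% (N2swap) and 57.6% (N3swap) were made again, and 21.3% and 43.1% without N2swap replicate 3 and N3swap replicate 1, while the Gapdh control (0.19 ± 0.17 and 0.22 ± 0.13 against 0.16 ± 0.01 with the vector, SD) moved less than Actb. A wrong label or a shared batch of the swap arrays was not tested. For genes changed at least 1.5-fold, copy number of whole chromosome stretches as the whole cause is argued against. The lowest share still so changed without their stretch median was 74.4% (HMGN3a in MIN6 cells). For smaller changes it stays open, and in that pool 869 of the 4488 called genes reached 1.5-fold. The chromosome 15 stretch at -0.85 in the HMGN5 pool could reflect lower DNA copy number, which cannot be told apart from regulation because DNA was not measured. Stretches shorter than 50 genes and the founding of a pool from few cells stay open, as does an effect of the constructs.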

How the results depend on the processing

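The covariates for male cells and for the Actb difference, and leaving out both divergent swap arrays, were chosen only after the result was seen; the other alternatives were planned before the data were examined. The cause of a moved count was not tested, except that testing every probe set tests more features and leaving out arrays uses fewer samples. Dim probe sets near the background limit what can be called.

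With every probe set tested the counts were 21 for the arrays labelled HMGN5 knock out, 35 for the difference of the HMGN1 and HMGN5 effects, 6492 for HMGN3 WT against HMGN1 WT, 10371 for HMGN2, 8851 for HMGN5, 4 for HMGN5SE, 8390 for N2swap, 8497 for N3swap and 6967 for HMGN3a in MIN6 cells. In the direct contrasts they were 8959 for HMGN5 against HMGN5SE, 10444 and 11524 for N2swap and N3swap against HMGN1, 12422 for N2swap against HMGN2 and 10059 for N3swap against HMGN3a. Quantile normalization again gave 92 for the HMGN1 knock out and 2 for HMGN3a in SV40 MEFs. It moved the share of higher calls from 23.2% to 38.4% for the difference of the HMGN1 and HMGN3 effects, from 18.2% to 30% for HMGN1 and HMGN5, and from 62.2% to 50.7% for HMGN1 in SV40 MEFs and MIN6 cells. With only the compared groups in the fit the limma counts were 7, 141 and 0 for the HMGN1, HMGN3 and labelled HMGN5 knock outs. For the last, 764 genes had an unadjusted p below 0.05 in the fit of all groups. With only the compared groups they were 177, 9 and 27 for the differences of HMGN1 and HMGN3, HMGN1 and HMGN5, and HMGN3 and HMGN5. For HMGN3a in SV40 MEFs the count was 0 (limma, 1746 at an unadjusted p below 0.05).

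The share of male cells as a covariate gave 82, 113 and 14 for the HMGN1, HMGN3 and labelled HMGN5 knock outs, with 35 of 60, 77 of 80 and 4 of 10 calls shared. Of 62 named gene values, 12 calls were lost with it and 1 was reversed. It gave 235 and 73 for the differences of HMGN1 with HMGN3 and HMGN5, and 2396 and 552 for HMGN3 WT and HMGN5 WT against HMGN1 WT. With it the difference of Xist between HMGN5 WT and HMGN1 WT was 0.22 (adjusted p = 0.908), the reverse of its direction without, and the covariate is itself read from sex-linked genes. The Actb covariate gave 4 for HMGN5SE and 3698 for N2swap against HMGN2 (2854 shared), and 2715 of 4989 and 2898 of 5030 calls were shared for N2swap and N3swap. With calls of at least 1.5-fold, the shared calls were 241 for HMGN1 and HMGN2, 120 for HMGN1 and HMGN5, 382 for HMGN2 and HMGN5, 705 for the swaps, and 77 and 77 for HMGN1 with N2swap and N3swap.

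The replicate numbers did not pair the arrays: in 0 of 20 comparisons did all 3 pairs of equal number correlate above 0.1 (range -0.34 to 0.38). With the replicate block the counts were 6 for the arrays labelled HMGN5 knock out and 2 for HMGN3a in SV40 MEFs, and within 1.5 times in the other comparisons.

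Leaving out each array in turn gave 18 to 62 for HMGN1 knock out against HMGN1 WT, 31 to 89 for HMGN3 knock out against HMGN3 WT, 5 to 23 for HMGN5 knock out against HMGN5 WT, 26 to 74 for the difference of the HMGN1 and HMGN3 knock out effects, 10 to 144 for the difference of the HMGN1 and HMGN5 knock out effects, 16 to 116 for the difference of the HMGN3 and HMGN5 knock out effects, 3045 to 4393 for HMGN3 WT against HMGN1 WT, 904 to 1502 for HMGN5 WT against HMGN1 WT, 1618 to 2235 for HMGN5 WT against HMGN3 WT. In SV40 MEFs and MIN6 it gave 3074 to 3443 for HMGN1 in SV40 MEFs, 4983 to 5513 for HMGN2 in SV40 MEFs, 1 to 4 for HMGN3a in SV40 MEFs, 4925 to 5115 for HMGN5 in SV40 MEFs, 2 to 2 for HMGN5SE in SV40 MEFs, 4176 to 5125 for N2swap in SV40 MEFs, 4129 to 4940 for N3swap in SV40 MEFs, 4992 to 5112 for HMGN5 against HMGN5SE in SV40 MEFs. For the rest it gave 5324 to 5981 for N2swap against HMGN1 in SV40 MEFs, 5843 to 6450 for N3swap against HMGN1 in SV40 MEFs, 5785 to 6568 for N2swap against HMGN2 in SV40 MEFs, 4867 to 5608 for N3swap against HMGN3a in SV40 MEFs, 39 to 91 for HMGN1 in MIN6, 3729 to 4120 for HMGN3a in MIN6, 2302 to 2781 for the difference of the HMGN1 effects in SV40 MEFs and MIN6, 2382 to 2659 for the difference of the HMGN3a effects in SV40 MEFs and MIN6.

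Of 67 list calls in the 12 knock out and construct comparisons, 7 were lost after quantile normalization, 5 without the filter, 0 with the block and 49 with an estimated correlation. For the direct and WT contrasts only the last was run. Of 169 named gene values, 4 calls were lost after quantile normalization, 3 without the filter, 4 with every probe set tested, 10 with the block and 30 with only the compared groups, and 0 were reversed in these settings. Other probe sets of a named gene lay on the other side of 0 for Fzd6 (0.02) and Nr4a2 (0.03) in the HMGN3 knock out, Ndufa12 (-0.27 and -0.16) in the arrays labelled HMGN5 knock out, Mycn (0.03 with HMGN3a, 0.01 with HMGN5SE) and Maf (-0.20 with HMGN1 in MIN6 cells and 0.05 in the difference between the lines), and limma called 0 of these 8. Some on the same side were also not called, as for Satb1 (-0.10) and Nr4a2 (-0.11) in the HMGN3 knock out. This held for Lgr5 (-0.02) between HMGN5 WT and HMGN3 WT, and for the other Ndrg1 probe sets (0.255 to 0.476) in the HMGN1 knock out. In that knock out it also held for Slco4a1 (-0.48), Dlgap5 (-0.235), Exo1 (-0.665), Mcm2 (-0.404) and the other Mcm7 probe sets (-0.425 to -0.378).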
